A study of Mus musculus with 4 samples.

How the data were processed

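The series holds 4 single-cell RNA libraries from mouse lungs, each the only library of its group, so there were no replicates. The groups cross a short hairpin against the glucocorticoid receptor gene Nr3c1 (shGR) or a control hairpin (shControl) in the injected 4T1 mammary tumour cells with the sorted population, tumour or niche. Per the labels' protocols, 500000 cells per mouse were injected, lungs were taken on day 7, and cells from different lungs were pooled. The tumour gate took living cells without CD45 and with tdTomato. The niche gate took living CD45-positive cells and then those stained for CD3, CD8 or CD49b in a shared channel. The labels also describe the niche samples by zsGreen, the fluorescent protein that the tumour cells secrete and neighbouring cells take up.

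The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode. Per the submitters' processing notes they come from Cell Ranger 8.0.1 and the mm10 assembly, and the chemistry per the labels' protocols was the 3' v3.1 kit with a target of 10000 cells and 50000 reads per cell. Gene and barcode lists were used for all 4 libraries, and the count matrix only for the library labelled shGR niche. The matrices of the other libraries were not used here, so expression was not compared between shGR and shControl. All 4 gene lists held the same 32285 identifiers, none of them named for the reporters. Of these, 32235 matched GENCODE release M21 (GRCm38, the same assembly as mm10), from which coordinates were taken.

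The deposited matrix held 13227 barcodes with 211959911 UMIs, a median of 4590 and a range of 500 to 258340 UMIs per barcode. Barcodes with at least 500 detected genes and under 10% mitochondrial UMIs were kept. Of all barcodes, 734 had fewer genes and 1037 had 10% or more, and 1300 failed either rule. Scrublet, as built into scanpy, marked only 2 of the remaining 11927 barcodes (0.0168%) at an expected rate of 8%. It did not work here, and doublets must be taken as still present among the 11925 kept barcodes.

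Barcodes were clustered with scanpy 1.11.5 (Python 3.11.15, igraph 0.11.9) on 2000 variable genes plus the fixed markers, 30 principal components, 15 neighbours and Leiden resolution 1 with random seed 1. Genes of the 13 outcome lists, a random 50% of all other genes without a role as marker (15992 held-out genes), and mitochondrial, ribosomal protein, histone and antigen receptor segment genes were kept out of the clustering. The marker lists, the outcome lists, the rule for named genes and the alternatives were fixed before the data were examined. A cluster took a cell type's name when at least 3 of its markers were detected and no other type had more markers among its 10 leading genes. Limits on mixing were set after the data were seen. Host classes needed under 300 CPM (counts scaled to a class total of 1000000) of the epithelial keratins Krt8 and Krt18 together. The tumour class needed under 25 CPM of Xist and of Ptprc. Clusters with at least 800 CPM of keratins and 25 CPM or more of Xist or Ptprc were called mixed and entered no comparison.

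Counts were summed over the cells of a class and divided by the class total to give CPM. Levels have exact 95% Poisson intervals, ratios exact conditional binomial intervals and shares exact (Clopper-Pearson) intervals. All of them cover counting error only, and no p-value was computed because cells of 1 library are not replicates. A gene was called higher in a class at a ratio of at least 1.5 with at least 20 CPM there, which is a rule of size, not a test. A count of 0 was set to 3 counts over the class, and the ratio is then a lower bound. A list's median ratio was placed among 10000 random lists of held-out genes of similar mean level. The lists cover the glucocorticoid receptor with its known targets, death receptors and apoptosis, cytotoxic granules, effector cytokines, inhibitory receptors, naive and memory T cells, tissue residency, NK receptors, interferon response, immediate early and dissociation stress, cell cycle, glycolysis and hypoxia. Of the list genes, 1 was absent from the gene list. Named genes are Nr3c1, Fkbp5, Tsc22d3, Fas and Fasl, up to 4 members per list with the largest ratio either way, and held-out genes among the 10 with the largest ratio per direction. Some genes that this rule takes are not reported here. Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs, and shallower cells were left out.

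The planned comparisons of NK with CD8 T cells, of CD8 with CD4 T cells and of regulatory with other CD4 T cells were not possible. Neither were those between clusters inside the NK and CD8 classes, because T cells formed 1 cluster and NK cells another. NK, T and B cells were compared as planned. Comparisons with tumour and endothelial cells and between clusters of macrophages and of tumour cells were added after the data were seen. The ratio and interval steps were tested on simulated counts with 200 changed genes. The counts were drawn from the Poisson model that the intervals assume, without variation between cells. The percentages that follow therefore check the calculation and are not error rates for these data. For NK against T, over 5523 genes, the interval held the true ratio for 92% of genes changed by 2-fold and 98% of those changed by 4-fold, and the size rule called 83% and 100% of them. It also called 2.01% of unchanged genes. For T against tumour, over 6167 genes, the interval held the true ratio for 95% of genes changed by 2-fold and 95% of those changed by 4-fold, the rule called 99% and 100%, and it called 0.0503% of unchanged genes. Alternatives were other filters, resolutions, clustering genes, scalings, depths and thresholds, with other random seeds, limits and subsets of cells added later.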

Results

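Single-cell RNA was measured in 4 pooled libraries from the lungs of mice that had received 4T1 cells, a mouse mammary tumour line that seeds the lung, carrying a hairpin against the glucocorticoid receptor (shGR) or a control hairpin (shControl). The barcode lists held 12567 barcodes for shControl tumour, 23007 for shControl niche, 14929 for shGR tumour and 13227 for shGR niche. The series addresses whether glucocorticoid signalling in tumour cells and the Fas death receptor pathway affect immune evasion during seeding. Expression was analysed in the library labelled shGR niche, so the comparisons below are between cell types inside that library. Each group had 1 library, all intervals are 95% counting intervals, and no difference has a replicate check.

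Barcodes were not shared between libraries beyond a low, even rate. The 6 pairs of libraries shared 52 to 100 barcodes. The product of a pair's barcode numbers divided by the shared number lay between 3043136 and 3615490 for every pair. The shGR tumour and shGR niche libraries shared 56 barcodes, 0.423% of the smaller list.

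The library labelled shGR niche held mainly keratin-rich barcodes and few lymphocytes. Clusters rich in the epithelial keratins Krt8 and Krt18 made up 78.3% of the 11925 kept barcodes (77.6 to 79.1). Of these, 3950 barcodes (33.1%, 32.3 to 34.0) formed a tumour epithelial-like class with a median of 20520 UMIs, and 5389 (45.2%, 44.3 to 46.1) were mixed, with keratin and host transcripts together and a median of 3528 UMIs. The division between these groups moved with the random seed of the clustering, and the tumour class held 24.6% to 29.9% with the seeds added later. Xist, the X-inactivation transcript of female cells, lay at 1.79 to 8.65 CPM in tumour clusters and at 610 to 1130 CPM in named host clusters other than neutrophils, at 112 CPM. The tumour class was limited to under 25 CPM of Xist and of Ptprc, so its low Xist follows in part from its definition. Host clusters had no Xist limit. The keratin-rich content of the library goes against the labelled sort. Whether the library belongs to this sample could not be settled here, so shGR and niche stand for its label only.

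Named host cells were 21.1% of kept barcodes. Monocyte/macrophage-like cells came first with 839 (7.04%, 6.58 to 7.51), followed by 719 neutrophil-like cells (6.03%, 5.61 to 6.47), 316 endothelial-like cells (2.65%, 2.37 to 2.95), 297 T-like cells (2.49%, 2.22 to 2.79), 197 NK-like cells (1.65%, 1.43 to 1.90) and 102 B-like cells (0.855%, 0.698 to 1.04). T, NK and B cells together made 5.0% (4.61 to 5.40). Basophil-like and ILC2-like clusters held 21 cells each, and an unnamed cluster led by the surfactant gene Sftpc held 74. The sort asked for CD45 and for CD3, CD8 or CD49b, so these shares do not describe the lung. Keratin levels put tumour RNA at 4.40% of UMIs in NK cells, 4.02% in T cells, 4.23% in B cells, 2.89% in endothelial cells, 2.18% in neutrophils and 1.97% in macrophages, against 79.9% in the mixed class. These percentages count all Krt8 and Krt18 as tumour-derived. They would give 21.9% in the unnamed cluster, where Xist was at 546 CPM, so host keratins may raise them. Host classes were limited to under 300 CPM of keratins and mixed clusters to at least 800 CPM. Part of the contrast between host classes and the mixed class was therefore fixed by these limits.

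**Figure D1:**
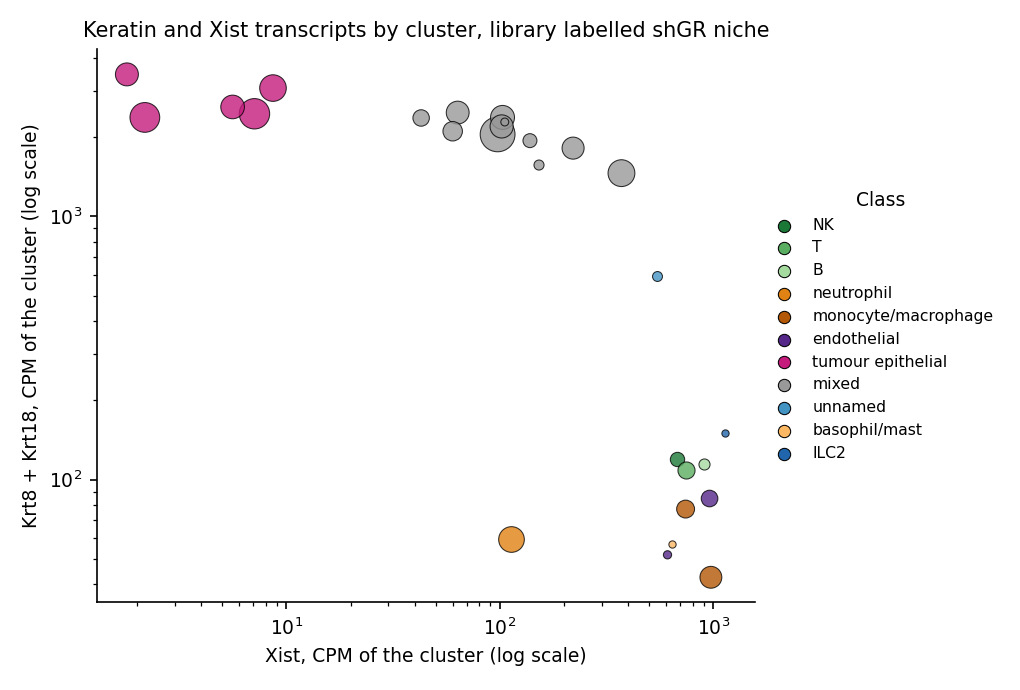
Each point is 1 of 27 clusters of the library labelled shGR niche, with Xist CPM on the horizontal and Krt8 plus Krt18 CPM on the vertical log axis, the area rising with the number of cells and the colour giving the class. Tumour clusters lie at 1.79 to 8.65 CPM of Xist, and mixed clusters at 42.8 to 371 CPM with keratins at 1461 to 2481 CPM. Limits of 25 CPM of Xist or Ptprc and 800 CPM of keratins define these classes, so their separation follows in part from the definition. Named host clusters other than neutrophils, at 112 CPM, lie at 610 to 1130 CPM.

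Nr3c1, which encodes the glucocorticoid receptor and is the target of the hairpin, was at 25.1 CPM (24.2 to 26) in the tumour class. It was higher in the 6 larger host classes: 596 CPM (554 to 640) in T cells, 371 CPM (327 to 420) in NK cells, 236 CPM (212 to 263) in endothelial cells, 171 CPM (132 to 218) in B cells, 166 CPM (158 to 174) in macrophages and 149 CPM (135 to 164) in neutrophils. The T over tumour ratio was 23.8 (21.9 to 25.7). Without shControl values this level is no measure of the knockdown. After thinning, 6.93% of 3537 tumour cells (6.11 to 7.81) and 46.9% of 290 T cells (41.0 to 52.8) had an Nr3c1 UMI, against 39.8% and 63.6% unthinned, with median depths of 20520 and 3971 UMIs. The gene lies on chromosome 18 from 39410545 to 39519421 (GRCm38, minus strand; ENSMUSG00000024431).

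The glucocorticoid targets did not share one order between T and tumour cells. Cell type and hairpin cannot be told apart here, since by the library's label only the tumour cells carry the hairpin. Of 13 list members at 20 CPM or more, 6 were higher in T cells and 6 in tumour cells, or 7 and 5 relative to the median of genes at that level in both classes. Higher in T cells were Tsc22d3, the anti-inflammatory leucine zipper GILZ, at 268 against 12.8 CPM (20.9-fold, 18.5 to 23.5), Zbtb16, a transcription factor of innate-like lymphocytes, by 180-fold (138 to 237), and Hsd11b1, which reactivates glucocorticoids, by 24.6-fold (15.7 to 37.4). Higher in tumour cells was Fkbp5, a receptor co-chaperone, at 64.8 against 33.7 CPM (1.92-fold, 1.42 to 2.67). Tsc22d3 reached 502 CPM (433 to 579) in B cells and 250 CPM (214 to 291) in NK cells, while Fkbp5 was at 82.4 CPM (62.3 to 107) in NK cells and 76.4 CPM (62.8 to 92.1) in endothelial cells. Tsc22d3 is on chromosome X (140539528 to 140600659) and Fkbp5 on chromosome 17 (28399094 to 28517527).

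Fasl, the ligand that triggers Fas on target cells, was mainly an NK transcript, and Fas was highest in endothelial cells. Fasl reached 352 CPM (309 to 399) in NK cells and 32.1 CPM (22.9 to 43.7) in T cells, against 0.179 CPM (0.114 to 0.269) in the tumour class and no UMI in B cells, which allows up to 8.01 CPM. A Fasl UMI was found in 55.4% of 166 thinned NK cells (47.5 to 63.1; unthinned 62.9%) and in 6.55% of 290 T cells (3.99 to 10.0; unthinned 12.1%). The share was 0.0283% in tumour cells, which should lack the gene (unthinned 0.557%). Median depths were 2917 UMIs in NK, 3971 in T and 20520 in tumour cells. T cells were 1 class, with Cd8a in 6.21% of the thinned cells, so Fasl was not compared between NK and CD8 T cells. Fas stood at 541 CPM (504 to 581) in endothelial cells, 134 CPM (121 to 148) in neutrophils, 63.4 CPM (50.2 to 79.0) in T cells, 38.2 CPM (34.5 to 42.2) in macrophages, 32.5 CPM (31.5 to 33.5) in tumour cells, 17.7 CPM (9.13 to 30.9) in NK cells and 2.67 CPM (0.0676 to 14.9) in B cells. The endothelial over tumour ratio of Fas was 16.6 (15.4 to 18). Fas lies on chromosome 19 (34290666 to 34327772) and Fasl on chromosome 1 (161780689 to 161788495).

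**Figure D2:**
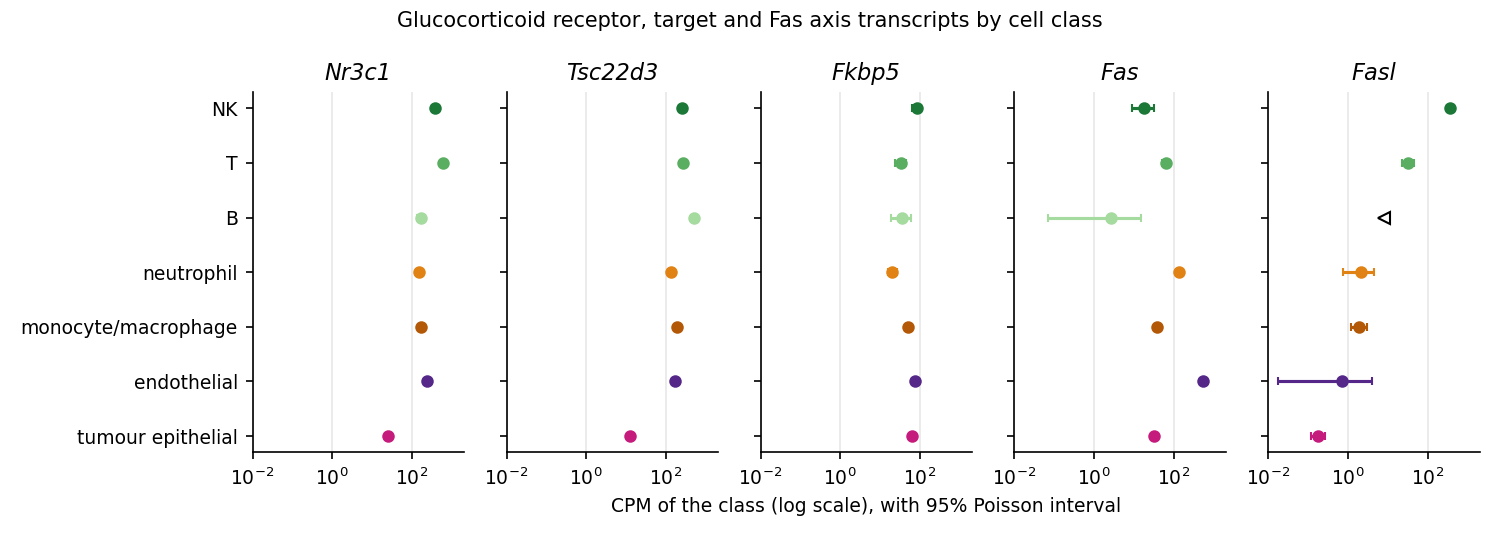
CPM of Nr3c1, Tsc22d3, Fkbp5, Fas and Fasl in 7 cell classes of the library labelled shGR niche on log axes, with 95% Poisson intervals as bars; the open triangle is the limit of 8.01 CPM that a count of 0 allows for Fasl in B cells. Nr3c1 and Tsc22d3 are lowest in tumour cells, Fasl is highest in NK cells at 352 CPM, and Fas is highest in endothelial cells at 541 CPM.

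Tumour cells carried far more proliferation and glycolysis transcripts than T cells. All 50 cell-cycle genes at 20 CPM or more were higher in tumour cells, 48 of them relative to the median of genes at that level in both classes, with Hmmr, a spindle protein, 42.8-fold (14.6 to 207) and Cenpe, a kinetochore motor, 29.5-fold (13.5 to 80.4) higher. Of 11 glycolysis genes, 9 were higher in tumour cells, among them Tpi1 by 11.8-fold (8.21 to 17.6) and Pkm by 4.82-fold (4.19 to 5.58). The survival factor Bcl2 was 19.1-fold higher in T cells (18 to 20.2). Over the death receptor and apoptosis list, 8 of 15 genes were higher in T cells and 4 in tumour cells. In the interferon list, 5 of 8 genes were higher in tumour cells, including Bst2, a membrane tether of budding viruses, by 3.25-fold (2.67 to 3.99), while Ifi27l2a was 53.2-fold higher in T cells (48.6 to 58.2).

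NK cells differed from T cells by higher granule, cytokine and NK receptor genes, and T cells by higher naive and memory T cell genes. Of 10 cytotoxic granule genes 8 were higher in NK cells and none in T cells, with a median ratio of 12.3 above all 10000 random lists (percentile 100). Gzma, a granule protease, was 343-fold higher (248 to 490), Prf1, the pore-forming perforin, 67.0-fold (44.4 to 106), Serpinb9, a granzyme B inhibitor, 22.3-fold (16.3 to 31.4) and Gzmb, another granule protease, 22.2-fold (17.5 to 28.7). Of 9 effector cytokine genes 7 were higher in NK cells and 2 in T cells, although the ratio of Ifng, singled out after its values were seen, was 9.25 (5.99 to 14.8) and depended on the clustering genes. The chemokine Ccl4 was 220-fold higher (126 to 428), Xcl1 31.6-fold (18.8 to 57.2) and Ccl5 25.2-fold (23.7 to 26.8) in NK cells. Of 14 NK receptor and maturation genes, 12 were higher in NK cells, including Itga2, which encodes CD49b of the sort, by 52.0-fold (30.6 to 96.0), and the transcription factor Eomes by 29.0-fold (18.2 to 48.8). Fasl was 11-fold higher in NK cells (7.82 to 15.7), and Fas 3.59-fold higher in T cells (1.94 to 7.24).

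Of 8 naive and memory T cell genes, 6 were higher in T cells and 1 in NK cells. The lymph node homing receptor Ccr7 led with 119-fold (32.8 to 989), then S1pr1, needed to leave lymphoid tissue, with 27.9-fold (13.4 to 69.8), the interleukin 7 receptor Il7r with 11.8-fold (8.86 to 16.1) and the transcription factor Tcf7 with 8.66-fold (5.38 to 14.8). Of 6 interferon genes, 5 were higher in T cells, with Ifi27l2a by 17.4-fold (11.5 to 27.6), and Irf7 was 3.28-fold higher in NK cells (2.18 to 5.02). Inhibitory receptors went both ways: of 11, 6 were higher in NK cells, such as Cd244a by 33.0-fold (12.4 to 124), and 5 in T cells, such as Ctla4 by 16-fold (9.43 to 29.5) and Btla, without a UMI in NK cells, by at least 9.45-fold. Hif1a, the hypoxia-response factor, was 5.37-fold higher in T cells (4.10 to 7.14) and Hk2, a glycolytic kinase, 10.4-fold (3.88 to 39.0).

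The other lists differed less between NK and T cells. Their counts moved when ratios were taken relative to the median of the 4938 genes at 20 CPM or more in both classes, a log2 ratio of 0.21. Among 12 glucocorticoid receptor and target genes, 6 were higher in NK and 1 in T cells, or 4 and 2 relative to the median, with Hsd11b1 at 5.05-fold (3.24 to 8.08), Sgk1, a serum- and glucocorticoid-induced kinase, at 2.49-fold (1.81 to 3.44) and Fkbp5 at 2.45-fold (1.61 to 3.74) higher in NK cells. The apoptosis list had 4 of 12 genes higher in NK and 3 in T cells, or 3 and 4. Immediate early and dissociation stress genes had 3 and 1 of 10, or 2 and 2, with Nr4a1 3.16-fold higher in NK cells (2.61 to 3.83). Cell-cycle genes had 5 and 2 of 23, or 4 and 3. Glycolysis had 3 and 2 of 11, or 2 and 3, tissue residency 2 and 2 of 5, or 1 and 2, and hypoxia 1 and 1 of 4, or 1 and 2. Among held-out genes, Klra3, a Ly49 receptor, was 136-fold higher in NK cells (45.9 to 663), and Cd6, a T cell surface receptor, was 113-fold (20.1 to 4499) and Bcl11b, a T cell identity factor, 26.6-fold (12.1 to 73.1) higher in T cells.

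**Figure D3:**
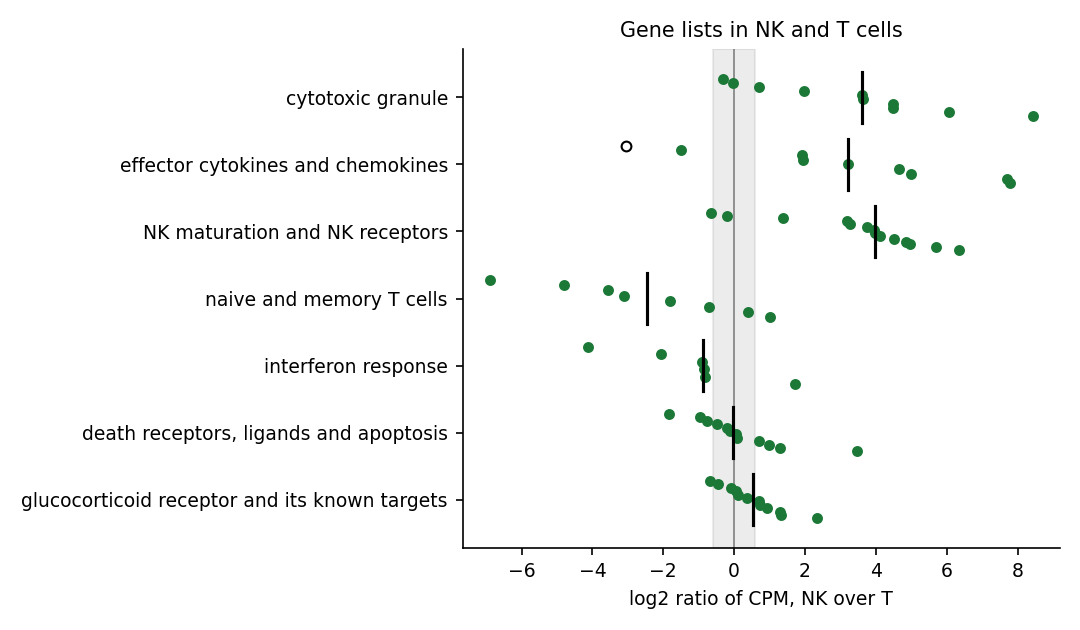
Log2 ratio of CPM, NK over T, for the members of 7 fixed gene lists with at least 20 CPM in either class; black bars are list medians, the grey band marks ratios within 1.5-fold, and the open circle is a bound from a count of 0. Granule, cytokine and NK receptor genes lie mostly to the right and naive and memory T cell genes mostly to the left.

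Most granule genes were lower in B cells than in NK or T cells. Against B cells, 8 of 10 were higher in NK cells and none in B cells, or 8 and 1 relative to the median of genes at 20 CPM or more in both classes, and 6 of 8 were higher in T cells. Gzma and Nkg7 had no UMI in B cells and were at least 1237-fold and at least 257-fold higher in NK cells. Nkg7 was at least 21.2-fold higher in T cells. Among apoptosis genes, 8 of 11 were higher in NK cells and 7 of 12 in T cells, with Bcl2 3.73-fold (2.94 to 4.78) and 5.24-fold (4.17 to 6.65) higher and Fas 23.7-fold higher in T cells (4.14 to 949). B cells had more Tsc22d3 than T cells, by 1.87-fold (1.56 to 2.25), and less Nr3c1, by 3.49-fold (2.70 to 4.57). All 6 interferon genes were higher in T than in B cells, although the interval of Gbp2 included 1 (2.40-fold, 0.946 to 7.80).

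In the T cells, CD4 transcripts were seen more often than CD8 transcripts. After thinning, Cd4 was found in 17.6% of 290 T cells (13.4 to 22.5; unthinned 26.9%), Cd8a in 6.21% (3.72 to 9.63; unthinned 9.76%), Foxp3, the regulatory T cell factor, in 6.21% (3.72 to 9.63; unthinned 6.73%) and Trdc, the gamma-delta receptor constant gene, in 7.24% (4.54 to 10.9; unthinned 8.75%), although Trdc was also found in 22.9% of 166 NK cells (16.7 to 30.0). None of 91 thinned B cells, with a median depth of 3097 UMIs before thinning, had a UMI of any of these genes, which allows a share of up to 3.97%. This limit overlaps the intervals of Cd8a and Foxp3 in T cells, so the few B cells alone do not separate them. Larger classes lay below those intervals at the same depth. Neither gene was found in 560 neutrophils (up to 0.657%). In 831 macrophages Cd8a was found in 0.361% (0.0745 to 1.05) and Foxp3 in 0.120% (0.00305 to 0.669). Thinning left out 7 of 297 T cells and 11 of 102 B cells. Cell-cycle transcripts of at least 2 listed genes were found in 98.8% of thinned tumour cells (98.3 to 99.1), 95.2% of NK cells (90.7 to 97.9), 77.2% of T cells (72.0 to 81.9) and 70.2% of neutrophils (66.2 to 73.9), a type that does not divide, so this share does not count dividing cells.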

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

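All tests in this part were chosen after the results they bear on were seen. The first pattern is the mixed clusters, a signal outside the compared classes that held 45.2% of kept barcodes. A single pool of free host RNA would keep host genes in one ratio, but that of held-out surfactant-cluster UMIs to held-out neutrophil UMIs spanned 635-fold, from 0.208 (at most 0.215) to 132 (at least 125), which argues against it. Reads exchanged with the shGR tumour library are argued against by only 0.482% of mixed barcodes (at most 0.706%) lying in that library's list. Droplets with a tumour cell of the tumour class's size beside a host cell should reach 20000 UMIs as often as tumour clusters, at 23.0% to 72.0% of barcodes, and are argued against in mixed clusters of at least 100 cells where at most 12.8% did, but stay open and cannot be told apart from other causes in those led by C1qa (37.8%) and Gzma (24.6%). Host cells or fragments carrying tumour-derived RNA and doublets of small tumour cells stay open and were not tested, and no biological explanation was tested. Keratin levels put tumour RNA at 79.9% (79.4 to 80.4) of the UMIs of the mixed class if all Krt8 and Krt18 are tumour-derived. The interval does not cover host keratins, which may be present in mixed clusters led by lung genes such as Sftpc.

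The second pattern is the endothelial class behind a sort for CD45. CD45-positive cells that picked up free endothelial RNA should carry Ptprc, the CD45 gene. Ptprc in this class was 8.93% (6.98 to 11.3) of the B cell level, which argues against that explanation. Incomplete sorting stays open and cannot be told apart from other causes, since the class is 2.65% of kept barcodes in 1 library and no second matrix of this gate was used here.

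The third pattern is the low Nr3c1 level of tumour cells. Dilution in their larger RNA pool would leave at least as many Nr3c1 UMIs per cell as in T cells. T cells held 2.50 and tumour cells 0.814 UMIs per cell, a ratio of 3.07 (2.83 to 3.33). Against the 1980 tumour cells with at least 20000 UMIs the ratio was 1.82 (1.68 to 1.98). Both argue against dilution as the whole cause of the difference from T cells. The ratio per cell was not taken for the other host classes. Unthinned, an Nr3c1 UMI was found in 40.2% of B cells and 38.5% of neutrophils, against 39.8% of tumour cells. The share was 49.7% in NK cells, 54.4% in endothelial cells and 66.2% in macrophages. Dilution therefore stays open for the host classes other than T cells. Knockdown is an open biological explanation and cannot be told apart from the level of the cell line, since the 25.1 CPM has no shControl value beside it here.

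The unnamed cluster of 74 cells held Sftpc at 149175 CPM, a lung epithelial signal in a library labelled as sorted for lymphocytes. The 1300 barcodes that failed the filter, together with the 2 doublets, held Krt8 and Krt18 at 1569 CPM once mitochondrial UMIs were set aside.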

How the results depend on the processing

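All alternatives with other seeds, limits of 50 or 150 CPM, subsets of cells by transcripts of the other origin or by 20000 UMIs were chosen after seeing the data. Across 20 settings, 370 alternative values were computed for 37 results. No ratio reversed direction, and a reversal was defined for ratios only, not for shares or counts. Of all values, 310 stayed within the interval or within 1.5-fold for counts, and 60 moved. Of the moves, 20 were among 185 values treated as secondary, such as Gzmb, Prf1 and Ifng in NK over T cells. The larger part of the moves was among the main results, such as the class shares. The tumour share of 33.1% became 26.2% with doublets kept, 31.4% and 28.6% at resolutions 0.6 and 1.6, 30.2% unfiltered, 32.0% with the stricter filter, 24.2% with all genes and 24.6% to 29.9% with seeds 2 to 6. The mixed share of 45.2% became 51.6%, 46.9%, 48.8%, 47.0% (strict), 54.3% and 47.6% to 53.5% in that order. Keeping 2 doublets alone moved both, so their division is not stable. Both groups together were 77.4% at resolution 1.6, 76.2% unfiltered and 77.6% with the lowest seed. T, NK and B cells were 4.61% unfiltered and 5.91% with the stricter filter, which gave 4.46% neutrophils, 6.17% macrophages and 3.29% endothelial cells. Macrophages were 6.09% unfiltered and 6.53% with the lowest seed, and endothelial cells 2.35% unfiltered and 2.35% with all genes. Nr3c1 in T over tumour cells was 15.9 with cells weighted equally, 26 without mitochondrial and ribosomal genes, 25.8 with median-of-ratios scaling, 25.9 in cells without transcripts of the other origin and 25.8 against tumour cells with 20000 UMIs. Tsc22d3 was 14.3 with cells weighted equally, and Fas in endothelial over tumour cells 13.8 without mitochondrial and ribosomal genes. Ifng in NK over T cells fell from 9.25 to 1.66 (1.19 to 2.31) with clustering features from all genes, while 6 to 7 effector cytokine genes were higher in NK cells under every alternative. Klf2 in T over NK cells went from 0.761 to 0.915 (0.824 to 1.02) without mitochondrial and ribosomal genes, and Nr3c1 in NK over tumour cells from 14.8 to 8.36 with cells weighted equally. Thinning to 1000 UMIs gave Fasl in 26.4% of NK and 2.03% of T cells and Nr3c1 in 4.2% of tumour cells. With 3 cell-cycle genes the shares were 78.9% in NK, 52.1% in T and 97.0% in tumour cells. With 2 genes but unthinned they were 94.3% in T and 99.8% in tumour cells. The cause of these moves was not tested beyond the fewer UMIs or cells that thinning and filtering leave. No paired analysis was possible because each group had 1 library and no test was made.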

Other observations

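Every comparison in this part was added after the data were seen. Endothelial-like cells stood apart from tumour cells by glucocorticoid targets and stress genes. Of 13 glucocorticoid receptor and target genes, 9 were higher in endothelial cells and 2 in tumour cells, with a median ratio of 6.57 at percentile 99.9 of random lists. By the library's label only the tumour cells carry the hairpin against Nr3c1, so cell type and hairpin cannot be told apart for this list. Zbtb16 was 613-fold higher (490 to 774), Klf9, a transcription factor, 18.1-fold (16.8 to 19.5), Txnip, an inhibitor of thioredoxin, 13.9-fold (12.6 to 15.2) and Tsc22d3 13.5-fold (11.8 to 15.5). All 12 genes of the immediate early and dissociation stress list, which marks tissue handling too, were higher alongside them, with Fos at 3213 against 286 CPM and the chaperone Hspa1a 346-fold higher (271 to 448). Tnfsf10, the ligand TRAIL, was 17.0-fold higher (14.9 to 19.3) beside Fas. Cell-cycle genes were higher in tumour cells in 49 of 50 cases and glycolysis genes in 10 of 11. The leading held-out genes included Ccl21a, a chemokine of lymphatic endothelium, at 499 CPM.

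The monocyte/macrophage class was made of a cluster of 510 cells rich in Chil3 and a cluster of 329 cells rich in C1qa. Held-out genes highest in the Chil3-rich cluster included Ear1, an eosinophil-associated ribonuclease, by 119-fold and Atp6v0d2, a proton pump subunit, by 116-fold. Sgk1 was 8.76-fold (7.92 to 9.71) and Tnf 7.35-fold (6.58 to 8.23) higher there, but their lists did not follow. Of 13 glucocorticoid receptor and target genes, 4 were higher in the Chil3-rich and 5 in the C1qa-rich cluster. Of 7 effector cytokine genes, 1 was higher in the Chil3-rich and 4 in the C1qa-rich cluster. In the C1qa-rich cluster, genes of other cell types were higher: S100a8 of neutrophils at 8165 against 778 CPM, Ngp of neutrophils 51.3-fold (33.8 to 81.6), Sftpc 22.8-fold (19.8 to 26.5) and Gzma 9.67-fold (6.8 to 14.1), as were 4 of 5 granule genes and 4 of 6 naive and memory T cell genes. RNA or cells of these types may therefore account for part of any gene higher there. Il10 was 5.88-fold (4.65 to 7.49) higher, and 5 of 8 interferon genes were higher, led by Ifi27l2a at 7.21-fold (6.69 to 7.78).

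A tumour cluster of 1024 cells carried interferon transcripts above the other 4 tumour clusters. Of 11 interferon genes 10 were higher, with a median ratio of 5.25, and Ifit3 was 24.7-fold (20.4 to 30.2), Rsad2 10.4-fold (9 to 12.0) and Gbp2 6.95-fold (6.69 to 7.22) higher. Tnfsf10 was 5.72-fold (5.16 to 6.36) higher in the same cells. The clustering used other interferon-induced genes, so this cluster is not independent evidence of the programme. With 5 other seeds the leading tumour cluster had 9 to 10 such genes, and at resolution 0.6 it had 6. Fas ranged from 15.2 CPM (13.0 to 17.5) to 46.8 CPM (44.3 to 49.4) over the 5 tumour clusters and did not follow the interferon genes alone, since clusters with Ifit3 at 2.52 and 1.12 CPM, against 30.0 CPM in this one, had Fas at 41.3 and 39.0 CPM. Nr3c1 ranged from 13.5 CPM (11.5 to 15.7) to 39.2 CPM (36.9 to 41.7).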
